A study of Danio rerio with 12 samples.

How the data were processed

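Total RNA of retinas of adult F3 zebrafish was sequenced as TruSeq libraries with paired reads of 100 bases, 12 samples to a lane, at 14 to 32 M reads per sample, per the labels' protocols. Base calling and alignment steps are named only by tool in the submitters' processing notes: CASAVA 1.8.2, cutadapt, FastQC, TopHat and Cuffnorm, with the genome build Zv9. Other versions, the annotation and any strand setting are not given in the sources used here, and no genome or coordinates were used.

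The deposited FPKM table gives fragment numbers scaled to gene length and library size for 32674 Ensembl genes, as Cuffnorm writes them, per the submitters' processing notes. The companion deposited table is a signal, not raw counts: fragment numbers per gene divided by a size factor per library. Its unit was read from the values, of which 98.3% to 98.6% per library were within 0.01 of a whole multiple of the library's own step, with a tail of fractional values. The planned count test was therefore not used. The main test was the one laid down for this case, limma on log2(FPKM + 1). The number of steps per library gave the depth of 2838155 to 6749644 assigned fragments, so low genes carry large counting error. In each table, 1 column of values has no name; it could not be given to a sample and was used in no step, and the sample labelled control replicate 1 was not analysed here.

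Groups came from the concentration in the labels, which call the 6 samples of each lineage biological replicates. Symbols came from the table for 20495 genes and from the reference list of names for 1553 more; 10626 genes had none. The RefSeq gene table of assembly GRCz12tu was used only for older symbols. Genes that are near-identical copies, such as tandem opsin genes, may share fragments, and their values are uncertain.

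Genes with a mean of at least 0.5 FPKM over the 11 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, Benjamini-Hochberg adjustment, threshold 0.05). Differences are MeHg lineage minus control lineage on the log2(FPKM + 1) scale, which understates the change of low genes. The standard error is the moderated one. Folds in the text are on the same scale. On simulated data for this comparison (20320 genes, 5 runs, 200 changed genes in each) the fit recovered 13.4% of 1.5-fold, 54.9% of 2-fold and 94.0% of 4-fold changes, and 6.01% of its calls were false. The changed genes were drawn only from genes above a floor of mean expression, so recovery in lower genes was not measured. Noise was drawn for each gene by itself, without effects shared across a library. Of 200 unchanged lists of independent genes 0 were called; the 5 lists shifted by 0.8 on the log2 scale were all called.

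Lists of genes for retinal cell types, neighbouring tissues, phototransduction, methylmercury chemistry, clock, chromatin and metabolism were fixed before the data were examined. A list needed 5 tested members. Each was tested against all other genes with camera at a preset correlation of 0.01, and again with an estimated correlation. With fry each list was tested by itself, without comparison to other genes, for a change in one direction on balance and for change in either direction. The genes named are, by a rule fixed in advance, the 12 with the smallest p in each direction that carry an assigned symbol, and up to 4 members with the smallest p of each list; clone-based names were counted but mostly not named. After the values were seen, 7 further lists were made: oocyte, vitellogenin, ovarian follicle and testis germ cell genes, clock activators with nfil3 genes, a group of per, nr1d, ciart and PAR bZIP genes, and light-induced genes of clock and DNA repair.

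Alternatives covered the pseudocount, filters, scaling, covariates, array weights, a replicate block, shared numbers, each library left out in turn and other thresholds. Several were added after the data were seen, among them leaving out control libraries 5 and 7.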

Results

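Retinal RNA of adult zebrafish was compared between a pair of lineages of the EK strain. Eggs of the founding F1 generation had been kept for 24 h in 0.03 µM methylmercury (MeHg, an organic form of mercury that binds thiol and selenol groups) or in 0 µM MeHg with the ethanol vehicle, and the fish analysed were of the F3 generation, which met no added MeHg. The question was whether the retinal transcriptome differed between fish whose ancestors had and had not been exposed. Of 12 labelled samples, 6 in each lineage, the 11 with a named column entered the comparison: 5 libraries of the control lineage (numbers 3, 4, 5, 7 and 8) and 6 of the MeHg lineage (numbers 2 to 7). Values were FPKM, fragment numbers scaled to gene length and library size, for 32674 genes. The companion table of scaled fragment numbers implied 2838155 to 5663021 assigned fragments per control library and 4354471 to 6749644 per MeHg library. Of all genes, 20320 had a mean of at least 0.5 FPKM and were tested.

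Genes of the circadian clock and the photoreceptor genes rho and arr3a were among the genes with the smallest p between the lineages. In total 1824 of the 20320 genes differed (limma, Benjamini-Hochberg adjusted p under 0.05), 1112 of them higher and 712 lower in the MeHg lineage, and 519 of the 1824 had no assigned gene symbol. At least a 2-fold difference on the log2(FPKM + 1) scale was reached by 567 of the higher and 416 of the lower genes. In 1294 of the called genes no value of one lineage overlapped the other, and such separation held for 7.52% of all genes tested against 0.433% given by chance. At an unadjusted p under 0.05 there were 4898 genes. Control libraries 5 and 7 held transcripts of oocytes, described below, and without them 1631 of 19697 genes were called, 716 higher and 915 lower. The 1173 genes called in both fits moved in the same direction in both. Without control library 5 alone the count was 1177.

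Among the 12 higher genes with the smallest p, the largest differences on the log2(FPKM + 1) scale were in nfil3-5 and nfil3-2, which encode bZIP transcriptional repressors of the clock output. The transcript of nfil3-2 (ENSDARG00000043237) rose from 8.21 ± 2.18 FPKM (SD, n = 5) to 289 ± 57.9 FPKM (SD, n = 6), a log2 difference of 4.99 ± 0.19 (SE; limma adjusted p = 3.11e-08). For nfil3-5 (ENSDARG00000094965) the log2 difference was 5.10 ± 0.25 (SE). The F-box gene fbxl3l went from 0.242 ± 0.327 FPKM (SD, n = 5) to 20.7 ± 5.23 FPKM (SD, n = 6). With a pseudocount of 0.1 its log2 difference of 6.41 exceeded those of nfil3-5 (5.23) and nfil3-2 (5.14). The transcript of inhbb, the beta B subunit of inhibins and activins, rose from 9.42 ± 1.78 to 172 ± 62.2 FPKM. The cryptochrome cry2b rose 3.96-fold, from 83.6 ± 13.7 to 332 ± 39.7 FPKM. The other members of this set were ccdc88aa (9.44-fold), the actin regulator marcksl1a (4.06-fold), lppr4b (4.84-fold), the RNA-binding protein gene mex3b (9.77-fold), the tetraspanin gene cd82a (3.97-fold), rimkla, an enzyme that makes N-acetylaspartylglutamate (8.14-fold), and the adhesion molecule gene igsf9b (4.08-fold). The lowest and highest values of the lineages did not overlap for any of these 12 genes.

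The 12 lower genes with the smallest p included rho, the rod opsin gene, which is treated separately below. The nuclear receptor gene nr1d2b (ENSDARG00000009594), a repressor within the clock, fell from 183 ± 63.5 FPKM (SD, n = 5) to 6.80 ± 2.15 FPKM (SD, n = 6), a log2 difference of -4.52 ± 0.26 (SE; limma adjusted p = 1.47e-06). The period gene per1b (ENSDARG00000012499) fell as well (log2 difference -4.41), and so did per3 (-3.39) and ciarta, another clock repressor (-3.58). Also in this set, ddb2, which binds UV-damaged DNA, went from 20.5 ± 2.34 to 1.48 ± 0.638 FPKM, and cry-dash, a cryptochrome of the photolyase family, from 25.7 ± 9.04 to 0.812 ± 0.490 FPKM. Cone arrestin, arr3a (ENSDARG00000056511), fell from 5571 ± 2572 to 245 ± 31.3 FPKM. Metallothionein 2, mt2, a cysteine-rich protein that binds metals, fell from 372 ± 102 to 48.2 ± 13.1 FPKM, a log2 difference of -2.92 ± 0.21 (SE; limma adjusted p = 9.16e-06). The set was completed by biliverdin reductase blvra (log2 difference -1.91), dhrs12 (-2.89) and the mitochondrial carrier gene slc25a47a (-1.82). Each of these 24 genes, 12 per direction, kept its call in every alternative fit that was run. This is not independent support, since the genes were chosen for small p in these same values. The zeros of rho also entered every fit.

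Of the 48 tested genes on the circadian clock list, 15 rose, 16 fell and 17 did not pass; adjusted over the list alone, 20 rose and 17 fell. The members moved in opposite directions, so the list did not shift as a whole against other genes (camera, median log2 difference 0.30, mean -0.13, tested direction up, adjusted p = 0.796), although fry with mixed directions, which asks whether members change either way and makes no comparison with other genes, gave an adjusted p of 1.14e-09. All 31 of these calls held without control libraries 5 and 7, and 30 of the 31 genes showed no overlap between the lineages.

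**Figure D1:**
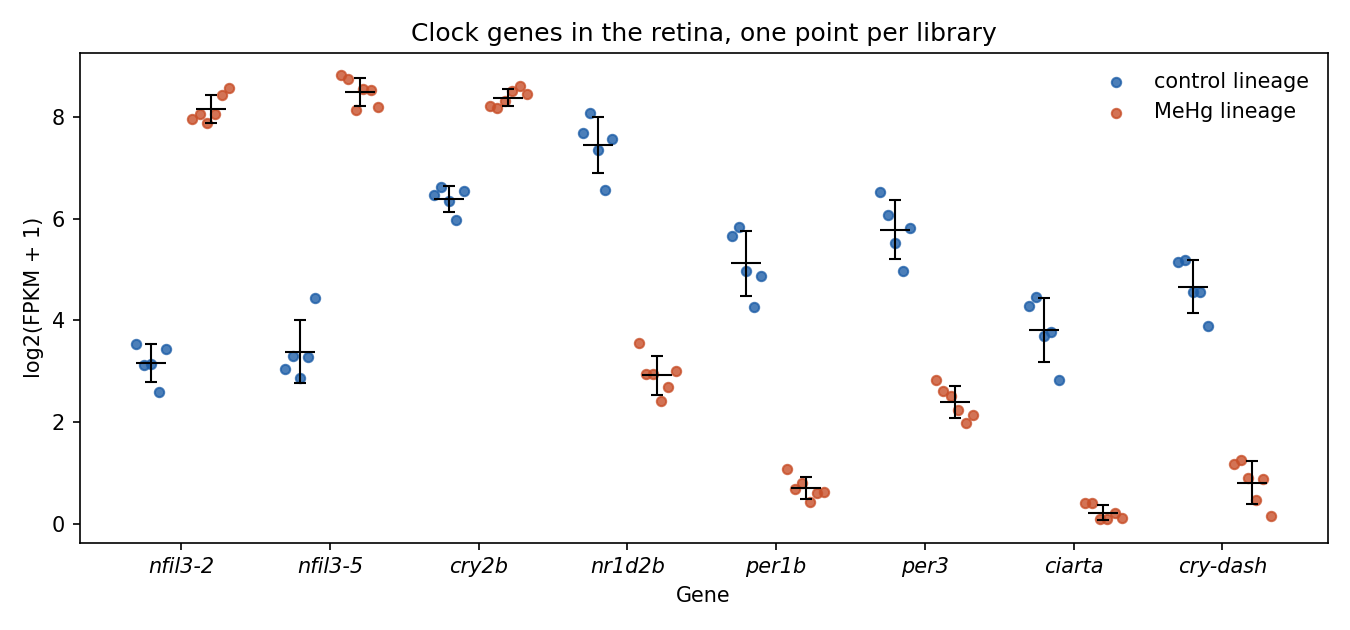
Expression of 8 clock genes as log2(FPKM + 1) per library, blue for the control lineage (n = 5) and orange for the MeHg lineage (n = 6), with the mean and SD as black bars. The genes nfil3-2, nfil3-5 and cry2b sit higher in every MeHg library, and nr1d2b, per1b, per3, ciarta and cry-dash sit lower in every MeHg library.

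Photoreceptor genes changed in both directions. The rhodopsin gene rho (ENSDARG00000002193) was listed at 0 FPKM in all 6 MeHg libraries, against 20297, 19675, 8682, 6346 and 13852 FPKM in control libraries 3, 4, 5, 7 and 8. It was the only gene listed at 0 throughout one lineage and at 1000 FPKM or more in every library of the other, and no fold is given for it because a value of 0 without counts can be a failed estimate. Apart from rho, 23 rod phototransduction genes were tested, of which 4 rose and 3 fell, with a median log2 difference of 0.46. Without control libraries 5 and 7, in which these genes were lower than in libraries 3, 4 and 8 (median log2 difference -0.93), 3 rose and 4 fell and the median was 0.12. The whole list of 24 had 5 higher and 4 lower when adjusted over the list alone. Rod arrestin sagb fell by 2.68 on the log2 scale and rgs9a, which speeds recovery of the light response, by 1.58, while guca1a, a guanylate cyclase activator, rose by 2.70. The list as a whole did not pass (camera adjusted p = 0.519), and its median (0.42) and mean (-0.30) differed in sign; its tested direction was up. Without control libraries 5 and 7 the median was 0.05, the tested direction was down and the camera adjusted p was 0.527, while directional fry called the list lower (adjusted p = 0.00191). With rho also left out, that fry value was 0.712. With all 11 libraries and without rho the camera adjusted p was 0.0845.

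Of 27 cone phototransduction genes 7 rose, 9 fell and 11 did not pass, with 10 and 11 adjusted over the list alone. Beside arr3a, the guanylate cyclase activators guca1g and guca1c fell by 4.92 and 3.22 on the log2 scale; guca1c went from 986 ± 446 FPKM (SD, n = 5) to 108 ± 59.5 FPKM (SD, n = 6). The list did not shift as a whole (camera adjusted p = 0.558; median 0.19, mean -0.47, tested direction down). Without control libraries 5 and 7, 5 rose and 11 fell, its median was -0.19 and directional fry called it lower (adjusted p = 0.0123), though camera did not (adjusted p = 0.0719). On the retinoid cycle list, which holds the enzymes that regenerate the visual chromophore, 1 of 21 genes rose and 6 fell, or 3 and 8 adjusted over the list alone. The gene that rose was lrata (limma adjusted p = 0.00358), with log2 differences of 2.23 to 2.80 over its alternatives. The largest falls were in rbp4l, from 7601 ± 5475 to 592 ± 80.5 FPKM, zgc:194355, from 77.1 ± 49.9 to 12.5 ± 5.21 FPKM, rpe65a, the isomerase of the pigment epithelium, from 507 ± 335 to 91.5 ± 28.6 FPKM, and rdh5, from 59.6 ± 34.7 to 11.2 ± 1.07 FPKM. The list was lower in the MeHg lineage by camera (median log2 difference -0.20, adjusted p = 0.0258), but not with an estimated correlation (adjusted p = 0.972). Without control library 3 its adjusted p was 0.0792 and without control library 8 it was 0.0741, within a range of 0.000275 to 0.0792 over its alternatives. Without control libraries 5 and 7 its median was -0.42 (camera adjusted p = 0.000416, and 0.943 with an estimated correlation; directional fry adjusted p = 0.00857), and it was the only one of 7 called lists to keep its call.

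**Figure D2:**
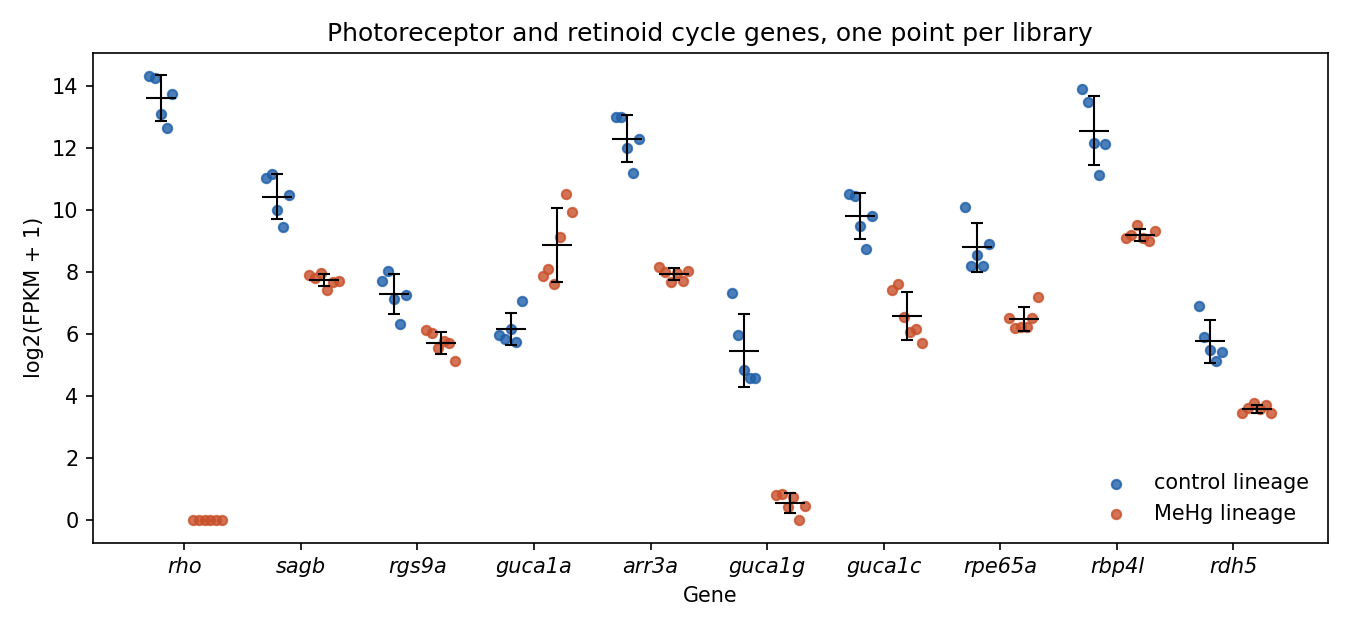
Expression of 10 photoreceptor and retinoid cycle genes as log2(FPKM + 1) per library, blue for the control lineage (n = 5) and orange for the MeHg lineage (n = 6), with the mean and SD as black bars. The gene rho is at 0 in all 6 MeHg libraries, guca1a sits higher in every MeHg library and the remaining genes sit lower; rho has no bar in the MeHg lineage.

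Among the lists of inner retinal cell types only the bipolar list was called by camera, and single genes were called in all but the amacrine list. Among 24 bipolar cell markers 4 rose and 1 fell, or 9 and 1 adjusted over the list alone: nyx, a protein of the ON bipolar synapse, rose 2.03-fold, samsn1a 2.16-fold and gnb3a 1.88-fold, while cabp5a fell from 1206 ± 504 to 478 ± 73.5 FPKM. The bipolar list was higher by camera (median log2 difference 0.48, adjusted p = 0.0153), but not with an estimated correlation (adjusted p = 0.972) and not without control libraries 5 and 7 (median 0.22, adjusted p = 0.324, within 0.00196 to 0.389 over its alternatives); without control library 7 alone it was 0.0908. Of 19 Muller glia markers 2 rose and 2 fell, or 3 and 3 adjusted over the list alone, among them fabp7a (2.91-fold higher), id2b (1.64-fold higher), the glutamate transporter slc1a2a (log2 difference -1.20) and apoeb (-0.78). Of 24 ribbon synapse genes 2 rose and none fell, or 3 and 1 adjusted over the list alone: the calcium channel gene cacna1fb (2.75-fold) and cacna2d4b (2.25-fold). That list did not pass (camera adjusted p = 0.165), but it was higher without control library 4 (adjusted p = 0.0193). Its median log2 difference was 0.17, and -0.10 without control libraries 5 and 7, where the vesicular glutamate transporter slc17a7a was also called lower (log2 difference -1.30, adjusted p = 0.00181). Among 13 horizontal cell markers only cx52.7 fell (log2 difference -1.27), with 1 higher and 3 lower adjusted over the list alone, and among 24 ganglion cell markers only neflb fell (-1.04), which was also the count adjusted over the list alone. The calls of gnb3a, id2b, apoeb, cx52.7 and neflb were each lost when single libraries were left out, with adjusted p up to 0.0716 (without control library 5), 0.0896 (control 5), 0.0769 (MeHg 6), 0.0840 (MeHg 2) and 0.0618 (control 5). The calls of gnb3a and id2b were lost as well without control libraries 5 and 7 together (adjusted p = 0.108 and 0.148). In that fit 2 bipolar markers were higher and 2 lower, 1 Muller glia marker was higher and 3 lower, and 0 horizontal cell markers were higher and 3 lower. None of 21 amacrine markers passed either way; the smallest p belonged to sst1.1 (log2 difference 0.91, adjusted p = 0.116). Of 56 genes of GABA, dopamine and glutamate transmission 6 rose and 6 fell, or 8 and 7 adjusted over the list alone. The counts were 3 and 9 without control libraries 5 and 7, and the median log2 difference was -0.10 in place of 0.13. The rho-type GABA receptor subunits moved apart, gabrr3a up 8.01-fold and gabrr1 down by 2.56 on the log2 scale, and the glutamate transporter slc1a7a rose 3.97-fold.

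Genes tied to the chemistry of methylmercury and to cell stress were called in both directions, except tubulins, which in the main fit were called higher only. Of 42 genes of the metallothionein, glutathione and NRF2 response 4 rose and 2 fell, and the same counts held adjusted over the list alone. They were 2 and 3 without control libraries 5 and 7. The fall of mt2 stood beside a rise of fth1b, a ferritin heavy chain (2.64-fold), and hmox1a, heme oxygenase (2.80-fold), and a fall of gsto1 by 0.93 on the log2 scale. Of 31 selenoprotein genes 3 rose and 2 fell, with the same counts adjusted over the list alone, including msrb1b (log2 difference -1.04), the deiodinase dio2 (50.2 ± 27.5 FPKM in the MeHg lineage, higher) and sepn1 (2.41-fold higher). Of 16 tubulin genes 3 rose and none fell, or 3 and 1 adjusted over the list alone: tubb5 3.88-fold, tuba1c 2.11-fold and tuba1b 1.77-fold. The tubulin gene tuba8l was not called in the main fit but was called lower in 6 of 24 alternative fits. Without MeHg library 4 its log2 difference was -1.58 (limma adjusted p = 0.00574). The call of tuba1b held in 8 of the 24. The calls of sepn1 and tuba1b were lost without single libraries, with adjusted p up to 0.0711 (without control library 8) and 0.0990 (MeHg 7), and without control libraries 5 and 7 (0.0738 and 0.168). None of these lists passed as a set (camera adjusted p = 0.524, 0.796 and 0.165). In the heat shock and unfolded protein response list 3 of 47 genes rose and 10 fell, or 4 and 13 adjusted over the list alone. The stress-induced pseudokinase trib3 rose 6.99-fold, and hsf2, a heat shock factor, fell by 2.42 on the log2 scale, hspe1 by 1.18 and hspd1 by 1.31; the latter pair encode the mitochondrial chaperonin. That list was lower by camera (median log2 difference -0.41, adjusted p = 0.00264), but not with an estimated correlation (adjusted p = 0.972), and without control libraries 5 and 7 its median was -0.17 and its adjusted p 0.0719, within 5.18e-05 to 0.0866 over its alternatives.

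For chromatin modifiers, 4 of 55 genes rose and none fell, or 2 and 0 adjusted over the list alone: the histone demethylase kdm6bb (2.91-fold), hdac6 (1.91-fold), hdac1 (1.34-fold) and tet2 (1.61-fold). The calls of hdac1 and tet2 were lost without control library 5 (adjusted p = 0.103 and 0.108) and without control libraries 5 and 7 (0.112 and 0.190). Of 92 nuclear-encoded genes of oxidative phosphorylation 0 rose and 3 fell, with the same counts adjusted over the list alone, all of succinate dehydrogenase or its assembly: sdha, sdhaf2 and sdhaf3, with log2 differences of -1.20, -0.81 and -0.98. That list did not pass (camera adjusted p = 0.646; median 0.02, mean -0.02, tested direction down), but it was lower without control libraries 5 and 7, where 7 members fell (median -0.18, adjusted p = 0.000416, within 0.000248 to 0.907 over its alternatives), and not then with an estimated correlation (adjusted p = 0.943); without control library 7 alone its adjusted p was 0.0377. Of 13 mitochondrially encoded genes none passed, nor did any adjusted over the list alone; mt-atp8 was at 16508 ± 10368 FPKM (SD, n = 5) and 14836 ± 10579 FPKM (SD, n = 6). Among 30 immediate early genes ier5 rose 2.16-fold while dusp5 and klf6a fell by 0.96 and 0.68 on the log2 scale, with 1 higher and 2 lower adjusted over the list alone. Without control library 5 the adjusted p of dusp5 and klf6a was 0.0593 and 0.0758, and without libraries 5 and 7 that of klf6a was 0.0926. Of 21 cholesterol synthesis genes sc5d rose 1.94-fold, with 2 higher adjusted over the list alone. That list did not pass (camera adjusted p = 0.0933) but was higher without control library 4, MeHg library 2 or MeHg library 4 (adjusted p = 0.0223, 0.0156 and 0.0463). Of 45 proteasome genes none passed either way, psmd11b having the smallest p (log2 difference 0.42).

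Markers of neighbouring tissues measured what else the samples held. Control libraries 5 and 7 carried 0.426% and 0.962% of their fragments in 34 oocyte genes, a list made after the values were seen, against 0.000238% to 0.00176% in the other 9 libraries. The egg coat gene zp3.2 reached 415 and 716 FPKM in these libraries and at most 2.46 FPKM elsewhere. The lists of cell cycle, skeletal muscle, skin and ribosomal protein genes were lower in the MeHg lineage by camera and were not called without these libraries. Their medians then moved by different amounts, and that of the ribosomal list did not move toward 0. The cell cycle list (32 genes, median log2 difference -1.26, adjusted p = 0.000463) then had a median of 0.04 (adjusted p = 0.726, within 4.55e-06 to 0.726 over its alternatives), and none of its members passed in either direction, also adjusted over the list alone; ccnb1 was at 54.4 ± 75.5 FPKM (SD, n = 5) and 1.15 ± 0.871 FPKM (SD, n = 6). Of 29 skeletal muscle markers (median log2 difference -0.77, adjusted p = 0.00688; without both libraries -0.41 and 0.324) only eno3 fell, from 189 ± 96.6 to 72.0 ± 24.4 FPKM, which was also the count adjusted over the list alone. Without control library 5 its adjusted p was 0.0711, and without both libraries 0.107. None of 17 corneal and skin epithelium markers (median -1.14, adjusted p = 0.0277; without both libraries -0.91 and 0.324) or 83 ribosomal protein genes (median -0.15, adjusted p = 0.0258; without both libraries -0.16 and 0.0719) passed, nor did any adjusted over the list alone. Their lowest p values were those of krt97 (log2 difference -3.03, adjusted p = 0.0716) and rps6ka5 (0.67, adjusted p = 0.0842); 10 of the 83 are genes of S6 kinases, which share the start of the symbol but are not ribosomal proteins. Without MeHg library 3 krt97 was called (adjusted p = 0.0463), and without control libraries 5 and 7, 2 genes of the ribosomal list were called lower, rps8b and the S6 kinase gene rps6kal (adjusted p = 0.0496 and 0.0168). The skin list also lost its call without control library 5, 7 or 8 or MeHg library 6 or 7 (adjusted p = 0.0560, 0.0908, 0.152, 0.167 and 0.252), and the ribosomal list without control library 3 or 8 or MeHg library 5, 6 or 7 (0.186, 0.209, 0.241, 0.266 and 0.113). Each of these 4 lists had an adjusted p of 0.972 with an estimated correlation.

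Of 23 markers of the pigment epithelium and other pigment cells 3 rose and 2 fell, or 5 and 2 adjusted over the list alone, among them the melanosome gene pmelb (2.58-fold higher) and lrata (5.63-fold higher), with rdh5 and rpe65a lower; the list did not pass (adjusted p = 0.796). Among 22 vascular and connective tissue markers cdh5 rose 1.77-fold and vwf 2.34-fold, which were also the calls adjusted over the list alone (vwf without MeHg library 7: adjusted p = 0.0666). Neither was called without control libraries 5 and 7 (adjusted p = 0.0555 for cdh5 and 0.102 for vwf), nor was any other of the 22. Among 14 oligodendrocyte and myelin markers tspan2a rose 2.67-fold, also the single call adjusted over the list alone. None of 9 lens, 10 red blood cell or 31 immune cell markers passed, nor did any adjusted over the list alone; the smallest p in these lists belonged to cryba4 (log2 difference 0.86, adjusted p = 0.104), cahz (-0.43, adjusted p = 0.344) and csf1rb (0.89, adjusted p = 0.0643). The carbonic anhydrase gene cahz is on both the red blood cell list and the Muller glia list, so its change cannot be given to either. It was called lower without control libraries 5 and 7 (-0.86, limma adjusted p = 0.00898) and without library 7 alone (0.0357). The immune cell marker csf1rb was called higher without control library 3 or MeHg library 5 (0.0457 and 0.0488).

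**Figure D3:**
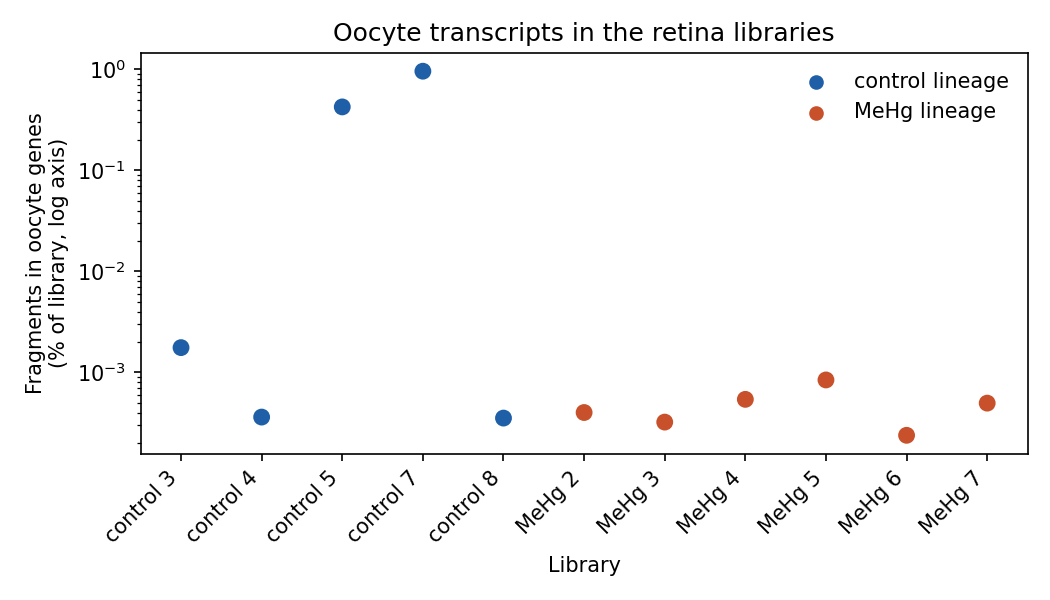
Share of each library's fragments that lay in 34 oocyte genes, in percent on a log axis, blue for the control lineage and orange for the MeHg lineage. Control libraries 5 and 7 sit at 0.426% and 0.962%, and the other 9 libraries lie at or below 0.00176%.

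Of 31 lists tested, camera with a preset correlation of 0.01 called 7, 1 higher and 6 lower in the MeHg lineage. None was called with an estimated correlation (smallest adjusted p = 0.972) or by fry for a common direction (smallest adjusted p = 0.166), whereas fry with mixed directions called 18. Without control libraries 5 and 7 directional fry called 3 lists, all lower: rod phototransduction, cone phototransduction and the retinoid cycle. With rho also left out it called 2, the latter pair (adjusted p = 0.0185 and 0.0171). Among 100 splits of the same 11 libraries into 5 and 6, 79 gave at least 7 called lists, the real split included, so the calls of lists were no more numerous than those of regrouped libraries. Without control library 8 the number of lists called was 4, and without control libraries 5 and 7 it was 2, the retinoid cycle and oxidative phosphorylation. The labels give neither the number of founding fish per lineage nor the time of day at which retinas were taken. The p-values measure the spread between libraries within a lineage. They do not measure how far lineages of the same exposure would differ.

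**Figure D4:**
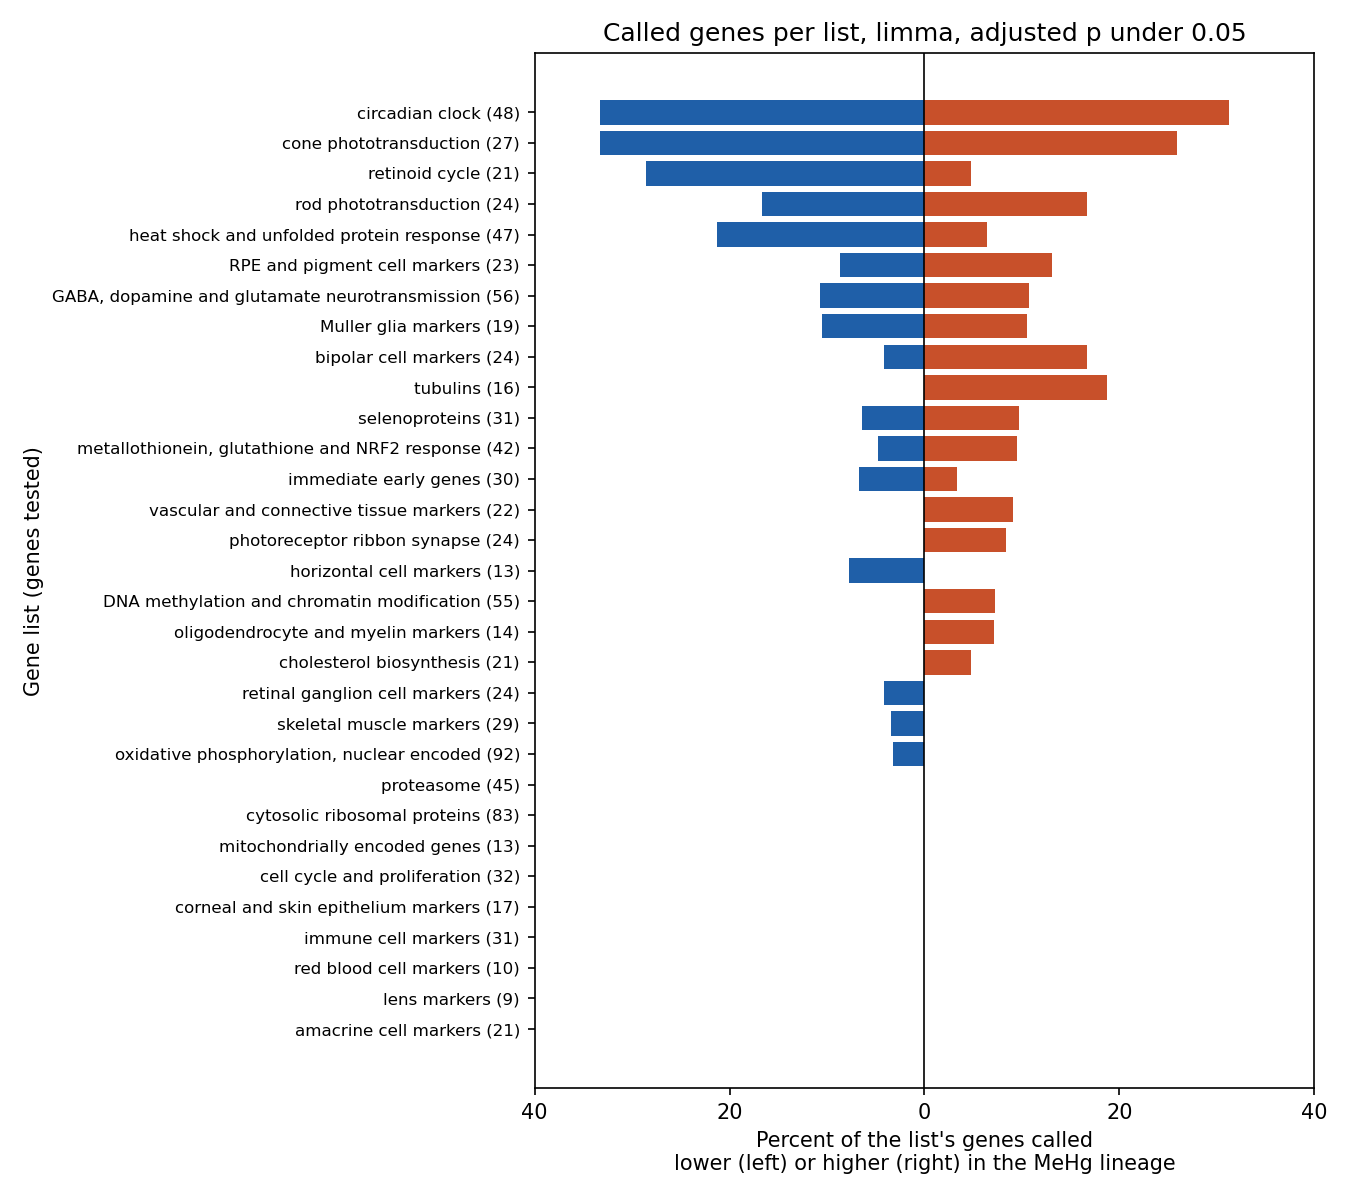
Percent of the tested genes of each of 31 lists that were called higher (orange, to the right) or lower (blue, to the left) in the MeHg lineage, with the number of genes tested in parentheses. The circadian clock list, with 15 higher and 16 lower of 48, shows the largest share of called genes.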

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

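The rule for values far from their group was laid down in advance, but not all items it was applied to. The cone opsin genes, zp3.2, vtg1, clocka, arntl1a and the oocyte share were added after the values were seen. The tests of explanations below were also chosen after the result was seen. In 366 groups of 5 or 6 values (149 genes, each list's mean per library and 3 properties of the libraries), 30 had a library whose distance from the nearest other value was too large a part of the whole range by Dixon's test at 95%. Chance alone gives about 18.3 over all these groups, the later items included.

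Among the control libraries, library 3 stood apart for blvra (22.0 FPKM), guca1g (159.7 FPKM), mbpb (17.3 FPKM), psmb7 (85.1 FPKM), rdh5 (119.7 FPKM) and rpe65a (1090 FPKM, against 291 to 484 FPKM in the others). Library 4 did so for cyp51 (13.4 FPKM), library 5 for opn1mw2 (332 FPKM) and library 7 for slc25a47a (11.4 FPKM). Library 8 did so for nfil3-5 (20.8 FPKM, against 6.29 to 8.79 FPKM), gata1a (1.34 FPKM), guca1a (132 FPKM) and opn1mw3 (732 FPKM).

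Among the MeHg libraries, library 2 stood apart for atp2a1 (65.5 FPKM) and library 3 for zgc:165571 (35.0 FPKM). Library 4 did so for pcna (71.7 FPKM), rps6ka3a (14.9 FPKM), rps6ka1 (10.9 FPKM), ctssb.1 (21.4 FPKM), cd59a (64.4 FPKM), tuba8l (57.6 FPKM) and myh11a (19.7 FPKM), and for the mean log2(FPKM + 1) of the myelin list (4.50) and of the cell cycle list (2.71, against 1.71 to 1.97 in the other MeHg libraries). Library 7 did so for tfap2b (43.0 FPKM), slc1a7a (35.2 FPKM), crybb2 (1.66 FPKM), rpe65a (147 FPKM), tuba1c (289 FPKM) and zp3.2 (0.4996 FPKM).

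The oocyte transcripts of control libraries 5 and 7 were weighed as a pattern. In 267 genes, with 3.05% and 6.93% of the fragments of these libraries, both exceeded every other library at least 20-fold; vitellogenin genes held 0.246% and 0.274%. A whole ovary sample under a retina label is argued against by rod genes other than rho, whose median log2 difference between libraries 5 and 7 and libraries 3, 4 and 8 was -0.93, with none below -1.32. For the oocyte genes, admixed ovary RNA of one composition is a candidate source: in 100% of 31 oocyte genes the ratio of library 7 to library 5 lay within 1.5-fold of the median of 2.05, against a median of 0.918 over other genes. It is argued against for the 7 vitellogenin genes, whose ratios were 0.820 to 1.31 (median 1.098), all outside that range, as were 47 of the 267 genes with these 7 included. Ovarian follicle genes were mixed. In libraries 5 and 7, cyp11a1 (16.0 and 35.1 FPKM), cyp17a1 (10.8 and 20.5) and hsd3b2 (3.63 and 14.5) exceeded every other library. By contrast foxl2 (0.916 and 6.55 FPKM against 17.2 in control library 3), and in library 5 also cyp19a1a and gsdf, did not. The remaining follicle genes were low. Whether follicle cells were part of such RNA is not settled by these values. Of the 34 oocyte genes 7 reached 1 FPKM in another library and 0 were on a list fixed in advance; how such RNA would have entered and where the vitellogenin transcripts came from stay open, and no biological explanation was tested.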

How the results depend on the processing

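Leaving out control libraries 5 and 7, the oocyte covariate, scaled counts, median-ratio and quantile scaling, the filter at 5 FPKM, array weights and rho left out of its list were chosen after seeing the data; the others were planned. The count of 1824 genes stayed within 1.5 times, at 1611 to 2019, with a pseudocount of 0.1, no filter or one at 5 FPKM, without libraries 5 and 7, with covariates, other scalings and array weights. It was 2746 at an adjusted p under 0.10 and 983 with at least a 2-fold change, both by construction. Leaving out each library in turn gave 1177 (without control library 5) to 1905 genes (without control library 3) and 4 (without control library 8) to 9 lists (without control library 4); the cause was not tested. Lists called numbered 2 without control libraries 5 and 7, 2 with the oocyte covariate, and 0 with an estimated correlation and 0 by directional fry, against 7. Directional fry without libraries 5 and 7 called 3, and 2 with rho also left out of its list; both fits were chosen after seeing the data. The cell cycle list changed direction, with a median log2 difference of 0.036 without libraries 5 and 7 and 0.084 with the oocyte covariate. That covariate is highest in these same libraries, so neither fit separates the oocyte transcripts from their other features. The share of higher calls, 61.0%, was 54.8% to 65.3% under other scalings, 43.9% without libraries 5 and 7 and 42.9% with the oocyte covariate.

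Numbers 3, 4, 5 and 7 occur in both lineages. The deviations of same-numbered libraries correlated at -0.20, -0.23, -0.01 and -0.13 over genes, and no control library correlated best with its own number. These values gave no sign of pairing by number. They cannot exclude it, because the oocyte transcripts of control libraries 5 and 7 could hide what same-numbered libraries share. With the number as a replicate block 159 genes and 5 lists were called, and the 8 libraries with shared numbers gave 784 genes without a block. The log2 differences in these fits are the same by construction, as for arntl1a (1.68) and opn1lw1 (2.33). With a term per number, libraries whose number occurs in only one lineage add nothing to the lineage difference. With the block the SE was close for arntl1a (0.184 against 0.179) and larger for opn1lw1 (0.477 against 0.396). The block also fits a term per number, which leaves fewer degrees of freedom to estimate the spread. How much of the gap between 784 and 159 this explains was not measured.

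Of 138 genes named by the rule, 80 were called, and 67 of these kept the call whichever single library was left out. Over all alternatives, 3040 gene results kept their side of the threshold, 183 lost the call and 68 gained it. For lists these counts were 520, 27 and 7, and 2 more, both of the cell cycle list, lost the call with a change of direction. Changes of direction in genes and lists that neither fit called were not counted apart and are included in the 3040 and 520. RLE and library-size normalization, DESeq2, voom with quality weights and the edgeR filters were not run, because the deposited tables hold no raw counts. Surrogate variables were not estimated either. In simulations 13.4% of 1.5-fold changes were recovered, so most changes of that size were not detectable here. Depth was not varied, and its part beside the number of libraries and the spread between libraries was not tested.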

Other observations

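Cone opsin genes, named here after their values were seen, were higher in the MeHg lineage, opposite to arr3a, guca1g and guca1c. The red opsin genes opn1lw1 and opn1lw2 rose by 2.23 ± 0.32 and 1.98 ± 0.31 (SE) on the log2 scale (limma adjusted p = 0.000961 and 0.00154), the green opsin genes opn1mw2 and opn1mw4 by 3.05 ± 0.65 and 1.39 ± 0.33 (adjusted p = 0.0117 and 0.0210), and the blue opsin gene opn1sw2 by 1.32 ± 0.24 (adjusted p = 0.00421). The green opsin opn1mw3 (641 ± 319 against 268 ± 263 FPKM, SD, limma adjusted p = 0.0833) and the UV opsin opn1sw1 (0.87, adjusted p = 0.0615) did not pass. The log2 differences of these 7 genes stayed above 0 in all 24 alternative fits; the calls of the 5 held in 23, 23, 22, 18 and 22 of them. The call of opn1mw4 was lost without control libraries 5 and 7 (adjusted p = 0.0915), with the oocyte covariate (0.0764) and without control library 5 or MeHg library 6 (0.0584 and 0.0501); its other losses, and those of the other 4 genes, were in fits with the replicate block or the 8 libraries with shared numbers. Of the pair that did not pass, opn1mw3 was called in 3 of the 24 fits and opn1sw1 in 4. For opn1mw3 these were without control library 8 (limma adjusted p = 0.00898), with quantile normalization (0.0428) and in the 8 libraries with shared numbers (0.0489). For opn1sw1 they were without control library 4 (0.0308), with median-ratio rescaling (0.0415), with quantile normalization (0.0179) and with the filter at 5 FPKM (0.0325). The green and red opsin genes are tandem copies that may share fragments, and single libraries stood apart for opn1mw2 (332 FPKM in control library 5) and opn1mw3.

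The tests in the rest of this part were chosen after the result was seen, except the splits of the libraries applied to lists. Among 100 of the 462 splits of the 11 libraries into 5 and 6, only 1, the real split, called 1824 genes or more. The highest other split called 566 genes; it set 5 of the MeHg libraries against the controls with the remaining MeHg library. The next called 2. The gene count was thus not matched by regrouping these libraries. The splits cannot exclude chance differences between the lineages, such as in their founding fish, or a difference of handling that follows the lineages. For lists, 79 of the 100 splits called 7 or more by camera at the preset correlation, and another split called 17, so chance was not excluded.

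The clock genes were weighed as a pattern, in groups put together after the values were seen. Of 10 clock activators and nfil3 genes 8 were higher and 1, nfil3-6, lower (log2 difference -2.16), with clocka up by 2.24 and arntl1a by 1.66. Of 14 per, nr1d, ciart and PAR bZIP genes 0 were higher and 11 lower. Of 7 light-induced genes of clock and DNA repair 0 were higher and 5 lower. This fall was not uniform, since the lineages overlapped for per2 and cry1a. The values of per2 were 43.9 to 169.7 FPKM in the control lineage and 56.9 to 72.6 FPKM in the MeHg lineage. Those of cry1a were 50.1 to 149.5 and 87.7 to 104.3 FPKM. Oocyte RNA in control libraries 5 and 7 is argued against, since all 31 clock calls held without them; under quantile normalization 31 held too. Collection of retinas at another time of day or light phase and a change of the clock passed on in the MeHg lineage stay open. That 19 of the 20 called genes in the activator and per groups moved in opposite directions supports neither, since the groups were made after these values were seen. The labels give no time of collection, so these cannot be told apart.

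The zero values of rho are the oddest single result. Loss of rods is argued against by the list as a whole. The other 23 rod genes had a median log2 difference of 0.46, and the lowest, sagb, was at -2.68. Without control libraries 5 and 7 the median and the lowest value were 0.12 and -3.15. Lost rods would take down the genes that only rods express. Genes of the list that cones may also express were not set apart, so the values were not weighed for rod-specific genes alone. A failed estimate may be the cause. If traces of other libraries' RNA in the lane were as large for rho as for oocyte genes, the MeHg library with the fewest would hold 62.8 rho fragments, yet 0 are listed. These traces varied across genes (0% to 0.876% of the fragments in control libraries 5 and 7, Spearman 0.48 over 27 genes), so the expectation is unsafe and a failed estimate stays open, as does a change of rho alone in the MeHg lineage, which was not tested.

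Of the other lists made after the values were seen, no oocyte (33 tested), vitellogenin (7), ovarian follicle (7) or testis germ cell (7) gene passed in limma at an adjusted p under 0.05.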
